A study of Solanum lycopersicum with 2 samples.

How the data were processed

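The 2 samples were small RNA libraries of tomato seedlings, a wild type control and stress-treated 7B-1. The authors deposited, per the file headers, a list of distinct sequences with an abundance for each library, and these values are counts of reads, whole numbers with no normalization, used as deposited. Per the labels' protocols, total RNA was extracted from stress-treated 7B-1 and wild type seedlings and pooled by genotype, RNA of 18 to 28 nt was taken from a gel, and libraries were made with the Illumina TruSeq small RNA kit. The lists hold sequences of 21 to 42 nt, so they extend past the stated gel range and miRNAs of 20 nt are not measured. The trimming program, length filters, aligner and genome build are not given in the sources used here. The labels conflict on the tissue, since the sample labels name seedlings and the series' design text names flower buds, and the sample labels were followed. They also conflict on whether the wild type seedlings were stressed, as the title says control.

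Library totals were 25158557 reads for the wild type and 41732777 for 7B-1, and 3 counts, the number taken as the limit that a count of 0 allows, equal 0.119 and 0.0719 RPM (reads scaled to a library total of 1e6). Sequences read once were 60.1% of the distinct sequences in the wild type and 70.1% in 7B-1, and the 10 most abundant sequences held 37.4% and 81.6% of the reads. These totals are of the listed lengths, not of whole libraries. The planned scale was RPM of all deposited reads. Because the kit's stop oligo dominated the 7B-1 library, results were also computed without reads that hold the 22-nt oligo within 4 edits (edlib). This choice was made after the data were seen. It took those reads out of both the numerator and the total, which left 25063280 and 8623689 reads. The 5' base shares of distinct sequences were not computed that way. TMM factors came from edgeR, on sequences with at least 10 reads in both libraries, and edgeR was used for nothing else.

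A list of 84 miRNA and related sequences, in groups by function, and a list of 14 rRNA and tRNA sequences were written from general knowledge before the data were examined. A family was the sum of reads of 19 to 24 nt that carry bases 3 to 18 of a listed sequence with a 5' end within 2 nt of the listed end. MiR482e-3p, the extended miR166 sequence and 7 rRNA and tRNA sequences (5 plastid and 2 nuclear) were added afterwards. Reads from rRNA and tRNA were exact parts of at least 18 nt. No genome was used, so no positions are given, and family membership by sequence does not tell near-identical loci apart. Names of rRNA and tRNA for sequences outside the lists come from general knowledge and were not aligned.

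With 1 library per group there was no test, p-value or standard deviation between groups. Ratios are 7B-1 over wild type on the log2 scale without a pseudocount, with 95% intervals from the Clopper-Pearson interval of the share of the 2 counts. A difference was called at 10 RPM or more in either library, at least 2-fold, with an interval that excludes 1-fold. This procedure was tested on simulated data drawn from the 2 libraries without the oligo, over 7981 sequences. It called 100 of 100 sequences changed 4-fold, 0 of 100 changed 1.5-fold and 0 of 7781 unchanged ones. The draws were Poisson counts around the mean of both libraries, with no variation between libraries. Changes were planted only at a mean of 20 RPM or more, so detection between 10 and 20 RPM was not tried. A change of 1.5-fold lies under the 2-fold rule. The result therefore covers counting error only and gives no error rate for calls between 2 single libraries. The named families are all those so called, up to the 15 largest per direction by log2 ratio, plus the 5 most abundant. The named unlisted sequences are the 5 with the largest log2 ratio per direction, computed with 1 count added, among those of at least 100 RPM in either library. Group medians took families of at least 5 RPM and were set against 10000 random lists of 20 to 22 nt sequences, each drawn from the 50 nearest in mean RPM. The Solanaceae and passenger strand groups had fewer than 2 such families and have no median.

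Alternatives planned before the data were examined were other denominators (reads of 18 to 28 nt, reads without listed rRNA and tRNA, listed miRNA reads, TMM), exact or 2-mismatch matching, 20 RPM added before the ratio, other thresholds of level and fold, distinct sequences counted once, removal of sequences read once or of the 10 most abundant ones, and thinning to equal depth. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, edlib 1.3.9.post1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.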

Results

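Small RNAs were sequenced from seedlings of tomato (Solanum lycopersicum, cv. Rutgers) in 2 libraries, a wild type control and a library of stress-treated 7B-1. 7B-1 is a male-sterile mutant line of this cultivar that the labels describe as stress-tolerant. The comparison asked which small RNAs differ in abundance between the mutant and its wild type under abiotic stress. Per the labels, seedlings grown under blue light at 23 °C were exposed to 10 µM abscisic acid, 140 mM mannitol, 120 mM NaCl or cold at 4 °C for up to 24 h, and RNA was pooled before library preparation. The wild type library held 25158557 reads of 1215228 distinct sequences, and the 7B-1 library held 41732777 reads of 675642 distinct sequences, all of 21 to 42 nt. Without the reads of a kit oligonucleotide described next, and with the wild type thinned to the 7B-1 depth, the order turned, to 608559 distinct sequences in the wild type and 660046 in 7B-1. Each group is 1 library, so no difference has a replicate check. The 95% intervals given throughout are exact (Clopper-Pearson) or derived from the conditional share of both counts, and they cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The labels call the wild type library a control, but the extraction text speaks of stressed seedlings of both genotypes, so genotype and treatment are not separated here.

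RNAs of 21 nt, the usual length of plant miRNAs, were the largest size class of plant sequence in both libraries. Most of the 7B-1 reads were a synthetic oligonucleotide of the library kit, the 22-nt stop oligo GAATTCCACCACGTTCCCGTGG. With its variants within 4 edits it took 79.3% of the 7B-1 reads (interval 79.32 to 79.35%) and 0.379% of the wild type reads (0.376 to 0.381%). The exact 22-nt sequence alone took 74.0% and 0.109%. In the wild type it had 27479 of the 95277 reads within 4 edits. Over all deposited reads, 14 sequences within 4 edits were at least 2-fold lower in 7B-1. The match may thus take in other RNA, and 0.379% may overstate the oligo in the wild type. Without these reads, 21-nt RNAs made up 30.3% of 25063280 wild type reads and 29.002% of 8623689 7B-1 reads, and 22-nt RNAs made up 5.49% and 4.81%. RNAs of 24 nt, the length of the small interfering RNAs that guide DNA methylation, made up 4.503% and 5.62%, a log2 ratio of 0.32. Length alone does not identify such RNAs. Of the 24-nt reads, 41.6% and 51.9% began with C and 35.9% and 27.4% with A, so the gain lay mostly with C. Over all deposited reads, dropping the 10 most abundant sequences of each library took 24-nt C reads from 471310 to 255368 in the wild type. In 7B-1 they went from 264038 to 126777, while 24-nt A reads did not change. Counted over all deposited reads, the 7B-1 shares were 6.44% at 21 nt, 78.6% at 22 nt and 1.21% at 24 nt, against 30.3%, 5.59% and 4.49% in the wild type, so the 22-nt and 24-nt ratios pointed the opposite way. Among distinct sequences without the oligo, 24 nt was the most frequent length, with 16.6% in the wild type and 14.2% in 7B-1, a log2 ratio of -0.23 that was -0.18 with the wild type thinned to the 7B-1 depth.

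**Figure D1:**
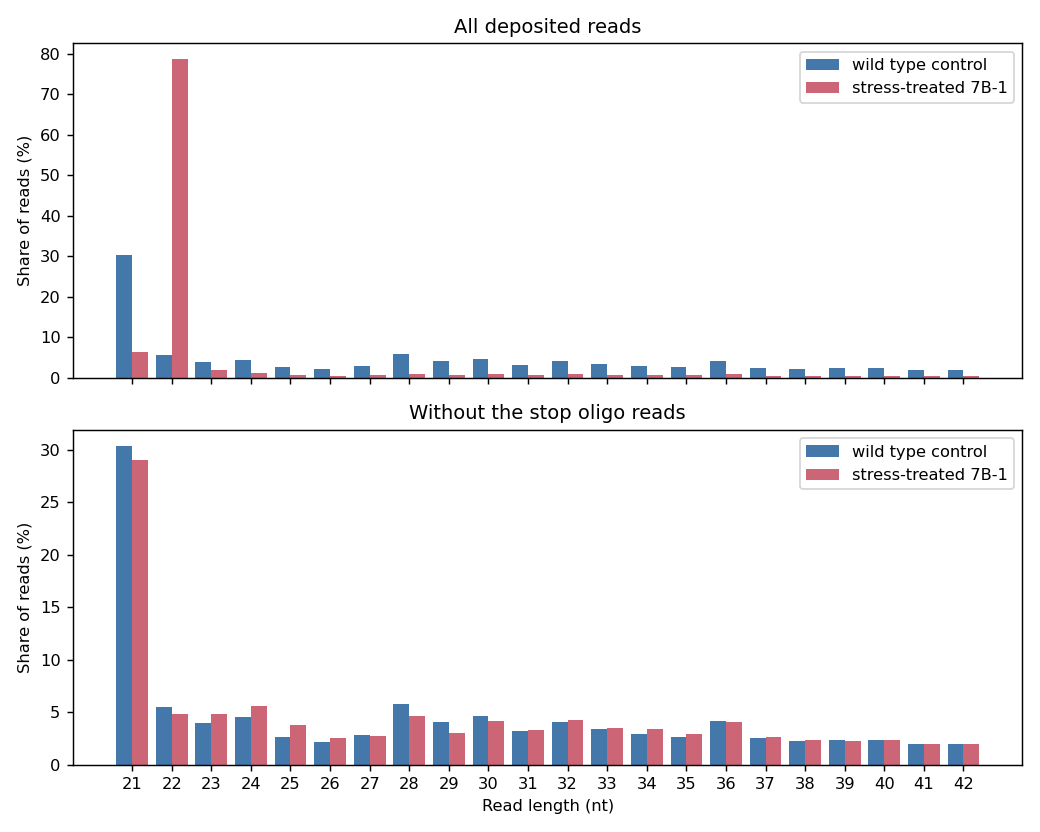
Share of reads (percent, vertical axis, from 0) at each read length (nt, horizontal axis) in the wild type control (blue) and stress-treated 7B-1 (red), over all deposited reads in the upper panel and without the kit stop oligo in the lower panel. At 22 nt the 7B-1 bar is 78.6% in the upper panel and 4.81% in the lower panel.

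The base at the 5' end, by which Argonaute proteins sort small RNAs, was mostly T at 21 nt in both libraries. Without the stop oligo, 86.3% of wild type and 83.7% of 7B-1 reads of 21 nt began with T, against 35.4% and 31.7% of distinct 21-nt sequences over all deposited reads, so this share rested on few abundant sequences. Of 22-nt reads, 50.6% began with T in the wild type and 27.6% in 7B-1, while those beginning with A made up 31.4% and 45.0%. These shares also rested in part on few abundant sequences. Over all deposited reads, dropping the 10 most abundant sequences of each library took wild type T reads from 695985 to 372194. In 7B-1 they went from 136951 to 130066. Reads beginning with A went from 432318 to 137359 in the wild type and from 210985 to 78756 in 7B-1. Distinct 22-nt sequences over all deposited reads, oligo variants included, began with T in 37.2% and 30.05%. They began with A in 25.1% and 20.8%. Of 24-nt reads, 35.9% and 27.4% began with A and 41.6% and 51.9% with C. Distinct 24-nt sequences, each counted once over all deposited reads, began with A in 63.3% of cases in the wild type and 60.6% in 7B-1.

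Most listed miRNA reads belonged to miR165/miR166, the family that controls HD-ZIP III transcription factors of leaf polarity and meristems. It took 24.9% of the wild type reads and 23.1% of the 7B-1 reads without the stop oligo, and 99.1% and 99.2% of all reads of listed families. Its most abundant sequence in both libraries, TCTCGGACCAGGCTTCATTCC, lies 2 nt upstream of the canonical TCGGACCAGGCTTCATTCCCC. The extended form outnumbered the canonical form 2.57 to 1 in the wild type (2.569 to 2.578) and 1.76 to 1 in 7B-1 (1.752 to 1.763). On the scale of reads without the stop oligo, the log2 ratio of 7B-1 over wild type was -0.27 for the extended form, 0.28 for the canonical form and -1.30 for miR166c-3p. With TMM scaling, a factor that centres the bulk of the sequences, the canonical form was at -0.11, so its direction turned, and the others were at -0.66 and -1.68.

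Of 47 listed families, which besides miRNAs include passenger strands and the TAS3-derived small RNA tasiARF, 36 had a read in these counts. The remaining 11 are not analysed here. A level of 10 RPM (reads per 1e6 deposited reads) in either library was reached by 11 families, and on this scale all 11 were at least 2-fold lower in 7B-1, with a median log2 ratio of -2.48. On that scale the median of 42079 sequences with at least 10 reads in both libraries was itself at -1.88. Without the stop oligo reads that median was 0.39, and with TMM scaling it was 0.0044. The family ratios below are therefore given without the stop oligo reads and with TMM scaling, the latter being relative to the typical sequence.

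MiR159 and miR1919 were at least 2-fold lower in 7B-1 on these 3 scales. With listed miRNA reads as the denominator, almost all of them miR165/miR166, miR159 was at -0.94 and short of 2-fold. MiR159, which targets GAMYB-like transcription factors of anther development, was counted 17367 times in the wild type and 2885 times in 7B-1. That is 690 and 69.1 RPM of deposited reads, or a log2 ratio of -3.32, which was -1.05 (-1.11 to -0.99) without the stop oligo and -1.44 with TMM. MiR1919, a family known from Solanaceae and here almost entirely its 5p arm TGTCGCAGATGACTTTCGCCC, had 1648 and 219 reads and log2 ratios of -3.64, -1.37 (-1.58 to -1.17) and -1.76 on those scales. MiR396, a regulator of growth-regulating factors, had 1887 and 402 reads and a log2 ratio of -0.69 (-0.85 to -0.54) without the oligo. MiR408, which targets copper proteins, had 1145 and 226 reads and -0.80 (-1.01 to -0.59), nearly all from variants of the listed sequence, which itself had 2 and 2 reads and no call. Both were past 2-fold with TMM, at -1.08 and -1.19, and over all deposited reads, at -2.96 and -3.07.

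Families with smaller differences included regulators of leaf shape, auxin response and the miRNA pathway itself. MiR319, which targets TCP transcription factors, had 4393 and 1306 reads and a log2 ratio of -0.21 (-0.30 to -0.12) without the stop oligo, and -2.48 over all deposited reads. Its listed sequence miR319a, with 1895 and 470 reads, was at -0.47 (-0.62 to -0.33) without the oligo. MiR162, which targets DICER-LIKE1, was at -0.16 (-0.31 to -0.01) without the oligo and -2.43 over all reads, from 1539 and 473 reads. MiR160, which targets auxin response factors, had 286 and 77 reads and -0.35 (-0.74 to 0.01), an interval that includes 0, against -2.62 over all reads. The whole miR165/miR166 family was at -0.11 and -2.38. MiR168, which targets ARGONAUTE1, had 11381 and 4737 reads and was at 0.27 (0.23 to 0.32) without the oligo but at -0.11 with TMM and -1.99 over all reads, so its direction depended on the scale. Its listed sequence miR168a-5p, with 2712 and 1295 reads, was at 0.47 (0.38 to 0.57) without the oligo, 0.09 with TMM and -1.80 over all reads. With TMM, miR319, miR162, miR160 and miR165/miR166 were at -0.60, -0.55, -0.74 and -0.50.

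**Figure D2:**
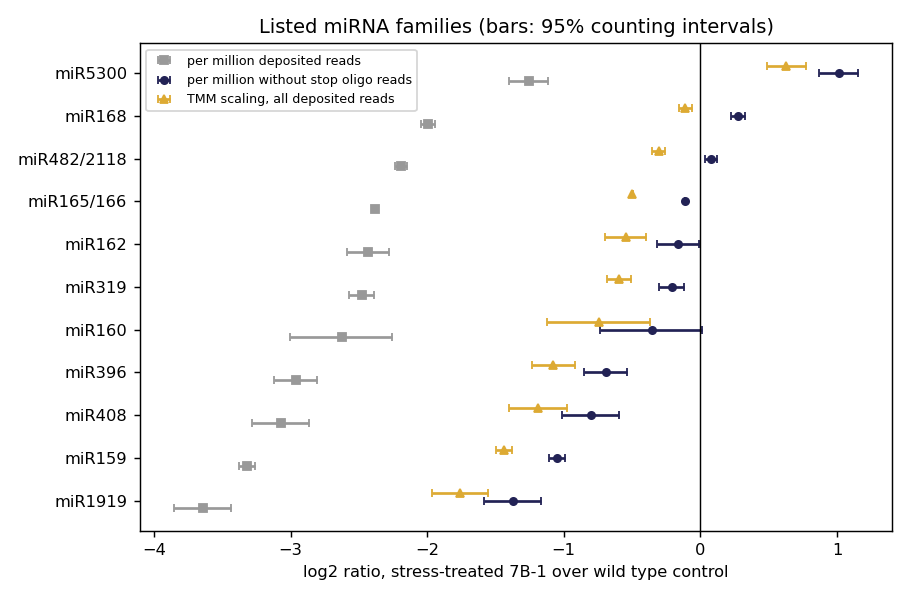
Log2 ratio of stress-treated 7B-1 over wild type control (horizontal axis) for the 11 listed miRNA families at 10 RPM or more (vertical axis), 1 library each, with 95% counting intervals as bars. Over all deposited reads (grey squares) all 11 lie below 0, without stop oligo reads (dark circles) miR168, miR482/miR2118 and miR5300 lie above 0, and with TMM scaling of all deposited reads (yellow triangles) only miR5300 does.

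The regulators of disease resistance genes differed from each other. MiR5300, a 22-nt miRNA that targets NBS-LRR transcripts, had 975 wild type and 677 7B-1 reads and had the highest ratio of the 11 families at 10 RPM. Its log2 ratio was 1.01 (0.87 to 1.16) without the stop oligo, or 38.9 against 78.5 RPM, and 0.63 with TMM, but -1.26 over all deposited reads. Its listed sequence alone, with 793 and 448 reads, was at 0.72 (0.55 to 0.88) without the oligo, short of 2-fold. The listed members of miR482/miR2118, which target the same gene class, summed to 14847 and 5395 reads and were at 0.08 (0.03 to 0.12) without the oligo, -0.31 with TMM and -2.19 over all reads. Within them, miR482b (TCTTGCCTACACCGCCCATGCC, 11723 and 4927 reads) was at 0.29 (0.24 to 0.34) without the oligo and -0.10 with TMM. MiR482a (TTTCCAATTCCACCCATTCCTA, 1053 and 71 reads) was at -2.35 (-2.72 to -2.004) and miR482c (TCTTGCCAATACCGCCCATTCC, 1627 and 222 reads) at -1.33 (-1.54 to -1.13), and both were lower with TMM as well, at -2.74 and -1.72. MiR482e-3p (TCTTTCCTACTCCTCCCATACC), added after its values were seen, had 84859 and 8135 reads, or 3386 and 943 RPM without the oligo, a log2 ratio of -1.84 (-1.88 to -1.81). Adding it to the family sum gave 99706 and 13530 reads and moved the family from 0.08 to -1.34 without the oligo and from -0.31 to -1.73 with TMM.

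**Figure D3:**
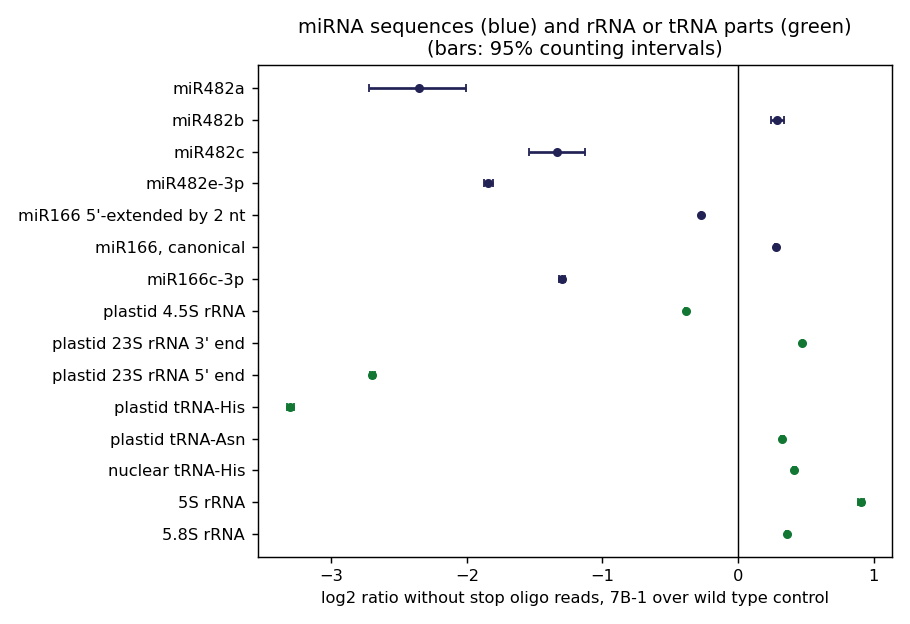
Log2 ratio of stress-treated 7B-1 over wild type control without stop oligo reads (horizontal axis) for single miRNA sequences (blue) and for sums of reads from rRNA and tRNA (green), with 95% counting intervals as bars. MiR482a, miR482c, miR482e-3p and miR166c-3p lie below -1, as do the 5' end of plastid 23S rRNA and plastid tRNA-His. MiR482b, canonical miR166, plastid tRNA-Asn and 5.8S rRNA lie above 0 here and below 0 with TMM scaling.

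Of the groups fixed before the data were examined, the nutrient and copper group was the lowest, with a median log2 ratio of -0.95 over miR398 and miR408, its 2 families of at least 5 RPM, without the stop oligo, at percentile 3.31 of 10000 random lists of 20 to 22 nt sequences matched on abundance. MiR398, which targets copper/zinc superoxide dismutases, had only 205 and 33 reads, and miR395 of the same group, below that level with 15 and 9 reads, was at 0.80 (-0.57 to 2.09). The 5 development families miR156/miR157, miR159, miR165/miR166, miR319 and miR396 had a median of -0.24 at percentile 8.58. The 2 auxin families miR160 and miR164 had a median of 0.02 at percentile 41.8, and the 2 small RNA pathway families miR162 and miR168 had 0.06 at percentile 35.7. For the 3 resistance gene regulators miR482/miR2118, miR5300 and miR6027 the median was 0.08 at percentile 37.2, and it was -0.94 with miR482e-3p in the family sum. Over all deposited reads, where the typical sequence was at -1.88, the medians were -3.22 for the nutrient and copper group, -2.51 for development, -2.25 for auxin, -2.21 for the small RNA pathway and -2.19 for resistance gene regulators. Their percentiles on that scale, the same with TMM, were 3.18, 2.46, 40.6, 12.41 and 26.05 in this order, among random lists that include stop oligo variants. For the small RNA pathway those lists had a median log2 ratio of 3.23, or 5.12 with TMM, so its 12.41 cannot place the group.

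Fragments of ribosomal and transfer RNA differed strongly by the molecule and by its end. Reads from the 5' end of plastid 23S rRNA, the large ribosomal RNA of chloroplasts, made up 1.52% of the wild type reads and 0.234% of the 7B-1 reads without the stop oligo, 6.48-fold lower. Reads from its 3' end made up 6.08% and 8.44%, a log2 ratio of 0.47 that was 0.09 with TMM. The plastid 4.5S rRNA, at 14.1% and 10.8%, was at -0.39. Plastid tRNA-His made up 1.24% and 0.126%, 9.87-fold lower in 7B-1, while nuclear tRNA-His made up 1.55% and 2.06% (log2 ratio 0.42, and 0.03 with TMM). These sequences were added after the data were seen. Of the RNAs listed beforehand, 5S rRNA was at 0.91 (0.89 to 0.93), the initiator tRNA-Met 5' part at 1.46 (1.36 to 1.56) and the tRNA-Gly 5' part at 1.25 (1.13 to 1.37), and these 3 stayed above 0 with TMM, at 0.52, 1.07 and 0.86. The tRNA-Ala, tRNA-Asp and tRNA-Glu 5' parts were at -0.32, -0.58 and -0.84, and 5.8S rRNA at 0.36, or -0.02 with TMM, while its listed variant (21052 and 6196 reads) was at -0.23, or -0.61 with TMM. The plastid tRNA-His 5' part listed beforehand, with 3753 and 147 reads, was at -3.13 (-3.38 to -2.90). Listed rRNA was 1.83% of the wild type and 2.44% of the 7B-1 reads without the oligo (log2 ratio 0.41, and 0.03 with TMM), but 1.82% and 0.504% over all deposited reads, so its direction turned. Listed tRNA was 0.119% and 0.106% without the oligo, and 0.119% and 0.0219% over all reads.

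Among single sequences of at least 10 RPM, 825 were at least 2-fold lower and 1190 higher in 7B-1, of 9068 without the stop oligo reads. With TMM scaling of the same reads the balance turned, to 1410 lower and 440 higher. Over all deposited reads, 6974 of 7292 were lower and 178 higher, and 153 of those 178 were variants of the stop oligo. Without the oligo, the 5 lowest and 4 of the 5 highest sequences outside the listed miRNAs resembled rRNA or tRNA. The 42-nt and 41-nt sequences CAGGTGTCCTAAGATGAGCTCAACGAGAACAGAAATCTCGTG and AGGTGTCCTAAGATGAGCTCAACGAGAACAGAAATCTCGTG, parts of cytosolic 25S rRNA, had 26813 and 30871 wild type reads against 270 and 461 in 7B-1, log2 ratios of -5.09 and -4.53 without the oligo. The other 3 lowest had log2 ratios of -6.04, -5.06 and -4.86. They were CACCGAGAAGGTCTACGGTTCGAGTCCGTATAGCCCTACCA and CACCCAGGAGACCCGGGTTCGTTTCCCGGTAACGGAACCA, which both end in the CCA of mature tRNAs, and CCCCCTGGGAAGTCCTCGTGTTGCATCC, which resembles the 3' end of 5S rRNA. Of the 5 highest without the oligo, 3 were nested fragments of cytosolic 18S rRNA. The longest, AGTATGGTCGCAAGGCTGAAACTTAAA, had 0 wild type and 1332 7B-1 reads, at least 1290-fold higher against a floor of 3 counts. The 26-nt and 25-nt forms had 1 wild type read each and 1185 and 1113 7B-1 reads, with log2 ratios of 11.75 (9.27 to 17.05) and 11.66 (9.18 to 16.96). A 31-nt sequence of origin not determined here had 1 and 1039 reads, at 11.56 (9.08 to 16.87), and a 25S rRNA part of 41 nt, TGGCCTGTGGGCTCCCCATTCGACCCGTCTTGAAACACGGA, had 103 and 1014 reads, at 4.84 (4.54 to 5.15). Over all deposited reads the 5 highest were all variants of the stop oligo.

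The libraries shared most of their reads but a minority of their distinct sequences. Without the stop oligo reads, 261725 distinct sequences were found in both, and these held 93.9% of the wild type and 94.5% of the 7B-1 reads. Of 9068 sequences with at least 10 RPM, 9033 were in both. Of miRNAs of other organisms used as controls, 4 sequences known from Arabidopsis and 5 from animals, no read was counted in either library, which allows up to 0.119 RPM in the wild type and 0.0719 RPM in 7B-1 over all deposited reads, or 0.12 and 0.348 RPM without the oligo.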

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

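The removal of the stop oligo reads and the addition of miR482e-3p were chosen after the results were seen, and the other settings in this part were planned. Signal appeared in kit sequence and at lengths past the stated gel fraction, above the limit that a count of 0 allows. The kit's stop oligo with its variants was 0.379% of the wild type and 79.3% of the 7B-1 reads, and its exact sequence 0.109% and 74.0%. Parts of the kit's 5' adapter were 0.112% of the wild type and 0.00223% of the 7B-1 reads. Reads of 29 to 42 nt, longer than the stated gel fraction, were 42.2% of the wild type and 8.79% of the 7B-1 reads, and 42.3% and 42.1% without the oligo.

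All 11 miRNA families past the level threshold were at least 2-fold lower in 7B-1 over all deposited reads. Removing the oligo reads raises every ratio by the same 2.27 on the log2 scale by construction, so the calls it ends restate the planned ratios on another scale. On that scale miR159 and miR1919 were still at least 2-fold lower, as was miR482/miR2118, at -1.34, once miR482e-3p was added to its members. With listed members only, 3 of the 11 families turned above 0 there, and of these miR5300 was at least 2-fold higher, at 1.01. TMM scaling kept 4 calls, miR159, miR396, miR408 and miR1919. With listed miRNA reads as the denominator, of which miR165/miR166 made up 99.1% and 99.2%, miR159 was at -0.94, short of 2-fold. Genotype and stress treatment stay untested as biological explanations, since each group is 1 library.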

How the results depend on the processing

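Every alternative that removes the stop oligo reads, thins the wild type library or adds miR482e-3p or plastid and tRNA-His sequences was chosen after the data were seen, and the others were planned. No paired analysis was possible because each group has 1 library, and for the same reason leaving out a library was not possible. Parts of at least 20 nt for rRNA and tRNA moved nothing, since the shortest sequence is 21 nt, so that setting says nothing about stability. Where no construction is named, the cause was not tested. Depth limits families below 10 RPM.

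The log2 ratio of the 21-nt share, -2.23 over all deposited reads, was -2.27 without sequences read once, -2.26 without listed rRNA and tRNA, 0.067 without the 10 most abundant sequences of each library, -0.00074 for distinct sequences, -0.064 without the stop oligo, -0.027 for distinct sequences without it and -0.061 for those with the wild type thinned. In that order of settings, the 22-nt ratio of 3.81 became 3.82, 3.80, 1.87, 0.19, -0.19, 0.016 and -0.0091. The 24-nt ratio of -1.89 became -1.98, -1.92, -0.26, -0.25, 0.32, -0.23 and -0.18. The ratio at 29 to 42 nt, a class outside the planned lengths, was -2.26 and became -2.34, -2.30, -0.40, 0.023, -0.0070, 0.038 and 0.034. Removing a 22-nt oligo that holds most of the 7B-1 reads is by construction what turned the 22-nt and 24-nt ratios. The setting without the 10 most abundant sequences keeps oligo variants, so its 22-nt ratio of 1.87 still carries them.

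The share of 21-nt reads beginning with T was 35.4% in the wild type and 31.7% in 7B-1 for distinct sequences, 49.9% and 29.5% without the 10 most abundant sequences, and 86.3% and 83.7% without the oligo. For 22-nt reads beginning with T these were 37.2% and 30.05%, 49.0% and 9.77%, and 50.6% and 27.6%. For 24-nt reads beginning with A they were 63.3% and 60.6% for distinct sequences and 44.3% and 36.1% without the 10 most abundant, and 27.4% in 7B-1 without the oligo. Both the distinct sequences and the setting without the 10 most abundant keep oligo variants, which mostly begin with G. In the latter setting G began 77.9% of 22-nt and 38.7% of 21-nt reads of 7B-1, against 10.2% and 2.19% without the oligo. The 7B-1 T shares of 9.77% and 29.5% are therefore lowered by construction.

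The count of families at least 2-fold lower, 11 as planned, was 4 with TMM, 2 with listed miRNA reads as the denominator (miR167 and miR1919, with miR159 at -0.94), 2 without the oligo (miR159 and miR1919), 3 without the oligo and rRNA or tRNA in the denominator, and 4 without the oligo with TMM. The count of families at least 2-fold higher, 0 as planned, was 1 with listed miRNA reads as the denominator and 1 without the oligo. The other 5 planned settings left the direction of all 11 families as it was, though miR160 and miR408 lost the call with exact matching, miR160 at -2.57 because its level of 8.82 RPM lay under the threshold and miR408 at -0.73, and miR160 and miR5300 lost it with 20 RPM added. MiR165/miR166 was at 0.00095 with listed miRNA reads as the denominator. This family held 99.1% and 99.2% of those reads, so its value lies near 0 by construction. The other families on that scale are in effect set against miR165/miR166. In the order listed miRNA reads, without the oligo, and without the oligo and rRNA or tRNA, miR482/miR2118 turned to 0.19, 0.079 and 0.039, miR168 to 0.39, 0.27 and 0.24, and miR5300 to 1.13, 1.01 and 0.97. MiR5300 was also at 0.63 with TMM and at 0.63 with TMM without the oligo.

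The group medians with TMM and without the oligo were -0.63 and -0.24 for development, -0.36 and 0.021 for auxin, -1.33 and -0.95 for copper, -0.31 and 0.079 for resistance gene regulators and -0.33 and 0.056 for the small RNA pathway. Families of at least 50 RPM gave -2.72 for development over all deposited reads, at percentile 0.96 of random lists. Those lists included stop oligo variants and had a median log2 ratio of 3.27, so this percentile cannot place the group. Without the oligo the development families of at least 5 RPM were at percentile 8.58. With miR482e-3p added, the resistance gene regulators were at -3.21 over all reads and -0.94 without the oligo.

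Sequences at least 2-fold lower numbered 6974 as planned, 1251 at 50 RPM, 25569 at 2 RPM, 4325 at 4-fold, 672 with TMM, 11511 with reads of 18 to 28 nt as the denominator, 1851 with 20 RPM added, 825 without the oligo and 1410 without it with TMM. Sequences at least 2-fold higher numbered 178 as planned, 105 at 50 RPM, 510 at 2 RPM, 385 with TMM, 1190 without the oligo and 440 without it with TMM. Thinned to the 7B-1 depth without the oligo, the wild type had 608559 distinct sequences, against 660046 in 7B-1. Listed rRNA was 1.83% and 2.44% without the oligo, listed tRNA 0.106% in 7B-1, and all listed and added sequences 27.1% and 5.20% of deposited reads, or 27.2% and 25.2% without the oligo.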

Other observations

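All tests in this part were chosen after the results were seen. A ladder of 1158 distinct sequences of 21 to 42 nt ended in GAGAACAGAAATCTCGTG, a part of cytosolic 25S rRNA, and summed to 189717 wild type and 3702 7B-1 reads. Without the stop oligo this was 17.6-fold lower in 7B-1, a log2 ratio of -4.14 (-4.19 to -4.09), while listed 5.8S rRNA was at 0.36 and 5S rRNA at 0.91. Plastid rRNA and tRNA sequences added after the data were seen together held 23.7% of the wild type and 20.6% of the 7B-1 reads without the oligo, and 23.6% and 4.25% of all deposited reads. Families below the level for naming differed in their ratios without the oligo. MiR398, miR167 and miR9471, with 205 and 33, 95 and 14, and 125 and 21 reads, were at -1.10, -1.22 and -1.03, while miR164, miR390 and miR156/miR157, with 137 and 62, 121 and 43, and 148 and 43 reads, were at 0.40, 0.047 and -0.24 with intervals that include 0.

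MiR5300, miR159 and the members of miR482 differed from each other in their ratios. Recovery that depends on read length would move miRNAs of equal length alike. The 22-nt miR482b exceeded the 22-nt miR482a by 2.64 on the log2 scale (2.29 to 2.99), so length alone does not account for this gap. The pair was picked after its values were seen. A length effect between miRNAs of unequal length, such as miR159 and miR5300, was not tested. Variation between any 2 libraries cannot be told apart from genotype or stress with 1 library per group, and both stay untested as biological explanations.

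Fragments of plastid RNA moved apart. A lower content of plastid RNA in 7B-1 would lower both ends of 23S rRNA alike, and its 3' end exceeded its 5' end by 3.17 on the log2 scale (3.15 to 3.19). A lower yield of fragments from 5' ends would lower the tRNA-His 5' fragments of nucleus and plastid alike, and the nuclear one exceeded the plastid one by 3.72 (3.69 to 3.75). These pairs were picked after their values were seen, so they show only that neither explanation alone accounts for the gap within its pair. No biological explanation was tested, and differences in RNA handling, library preparation or ligation by sequence were not tested and stay open.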
